A study of Homo sapiens with 9 samples.

How the data were processed

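DNA from normal brain, U87MG cells, glioblastoma, SssI-treated normal brain and GenomiPhi-amplified normal brain was compared on Agilent CpG island arrays. Per the labels' protocols, 750 ng of DNA was cut with 25 units of BfaI for 6 hours and joined to linkers, then split and cut with 20 units of HpaII or 40 units of MspI, and amplified by 16 cycles of PCR. The methylated control had been treated with 16 units of SssI and the amplified control started from 10 ng of DNA, per the labels. The HpaII product carried the red dye and the MspI product the green dye. Replicates were run on different days, and the GenomiPhi control had 1 array.

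The scanner files hold intensity values made with Agilent Feature Extraction, version 9.5.3.1 per the file headers and 10.5.3 per the submitters' processing notes. The processed intensity is background-subtracted, detrended and dye-normalised within each array but not between arrays, per the file headers. A deposited table gives the log2 HpaII signal per probe, which differed from the log2 of the scanner files' processed signal by about each array's dye factor. The score values of another deposited table were made by the authors as a z-score per BfaI fragment and array, averaged over the probes of the fragment, per the file headers. The population behind that score is not stated. The same table gives the number of HpaII sites per fragment. The genome build of the coordinates is not given in the sources used here, and coordinates are printed as the files hold them. Gene names were brought to current symbols with a RefSeq gene table (used for names only): of 13384 names in the files 10509 were current, 2346 were updated from a synonym and 529 were kept as in the files.

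Of 237220 probes, 8125 on the sex chromosomes or without a position were left out, which left 229095. The measure was log2 of processed HpaII over processed MspI signal, minus the array's median over 22910 reference probes, the 10% with the highest mean MspI signal. Of these reference probes 6.27% of those placed in a fragment lay in fragments without an HpaII site, so most of the brightest probes lay in fragments that MspI should cut. Gene values were means over at least 3 probes that name 1 gene, for 12829 genes. Probes with a value of at least 1 on both SssI arrays, 39159 in number, were called responding (informative) and gave 4630 genes; 15 of them lay in fragments without an HpaII site. The first 2 control comparisons used all autosomal probes, since the responding probes were chosen on the SssI arrays, and the other 4 used the responding probes.

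Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, 9 arrays, 5 groups, shared spread, two-sided), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Each adjusted p of a gene is from limma. Fixed gene lists, 16 in number, were tested with limma's camera at a preset correlation of 0.01, adjusted over 48 tests of lists and comparisons, and again with an estimated correlation. Those described here were HOX genes, other developmental transcription factors, clustered protocadherins, WNT antagonists, promoters discussed in glioma, imprinted, germline, housekeeping, histone, and ion channel and receptor genes, and markers of neurons, astrocytes, oligodendrocytes, immune cells, and endothelial and mesenchymal cells. Lists, comparisons, tests and the rule for named genes were fixed before the data were examined. Named were the 8 called genes with the largest difference in each direction whose arrays did not overlap between groups, per tumour comparison; the 2 largest called members in each direction of each list with a camera call or at least 3 called members; CDKN2A, CDKN2B, H19, MEST, SNRPN, SFRP1, GFAP and OLIG2 where measured; and 3 genes in each direction for the control comparisons. One list, and 6 values of genes that this rule named, are not reported here and were left out without replacement. Of 139 named values in the tumour comparisons 132 passed, and all 132 kept the sign of their mean relative to the all-gene median. That check could hardly fail, since the called differences exceeded these medians in size. Of the 132, 34 had at least 1 probe that went the other way, and 39 rested on a single fragment.

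The tests were checked on simulated data, with known changes added to 200 genes drawn at random. These data did not hold the real differences between groups: U87MG against brain gave 162 calls there and 1194 in the real data. The rates below belong to that setting. False calls numbered 12 of 162 for U87MG against brain, 4 of 149 for glioblastoma against brain and 12 of 159 for U87MG against glioblastoma. For U87MG against brain (4630 genes) 18% of changes of 0.5 were recovered, 94% of changes of 1 and 100% of changes of 2; for glioblastoma against brain 8%, 98% and 100%; and for U87MG against glioblastoma 22%, 88% and 100%. A shift of 0.5 added to the HOX list gave a camera p of 8.4e-32, and 0 of 15 other lists had a p under 0.05. Alternatives were the HpaII channel alone, the deposited log2 HpaII table, centring on all autosomal probes, normexp background correction with an offset of 50, single probes, a minimum of 1 probe, a filter on dim probes, other definitions of responding probes, the compared groups alone, a replicate block and leaving out each replicate. Normexp started from the raw mean signals, so it also left out the detrending and dye normalisation of the processed intensity. Added after seeing the data were centring on fragments without an HpaII site and on the responding probes, gene means of the authors' z-scores, scan day as a fixed or a random block, leaving out the GenomiPhi array, and promoter probes only for the lists. Replicate numbers matched scan days for normal brain and U87MG, with replicates 1 on day A and replicates 2 on day B. The correlation of replicate deviations was 0.09 between these groups and 0.41 between brain and SssI, and from -0.04 to 0.09 in the other pairs. Pairing across all groups was thus not shown, so the block on replicate numbers is an alternative only. Analyses of copy number in tissue and of sex chromosomes were left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, pyarrow 21.0.0 and matplotlib 3.10.9 were used for tables and plots.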

Results

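CpG island methylation was measured in human brain and glioma DNA on 9 dual-colour arrays. The DNA samples were normal brain, U87MG (an established cell line derived from a human glioblastoma) and glioblastoma tissue, with 2 arrays each. There were also 2 controls made from normal brain DNA. In the first, the bacterial methylase SssI had methylated CpG sites (2 arrays); in the second, amplification with the GenomiPhi polymerase kit had copied the DNA without its methylation (1 array). Each DNA was cut with BfaI and joined to linkers. One portion was then cut with HpaII, which spares methylated CCGG sites, and another with MspI, which cuts them regardless. A high log2 ratio of HpaII over MspI signal therefore marks DNA that HpaII left whole. From medians over all probes, the HpaII signal lay 3.45 to 13.4 times above background and the MspI signal 2.60 to 27.8 times, the highest value of each being that of the GenomiPhi array. The responding probes, used in the tumour comparisons, were dimmer. Their median log2 MspI signal was 8.21 in brain, 7.83 in U87MG and 8.08 in glioblastoma, against 9.73, 9.60 and 9.80 for all autosomal probes. Their ratios thus rest on weaker signals than the values over background show. The arrays of a group were technical replicates of 1 DNA, so every test below compares these DNA samples and not tissues at large, and the number of arrays limits its precision.

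The methylated control was compared with untreated brain DNA, to see whether the assay reads added methylation, and with the amplified control, whose single array was assumed to vary like the others and whose ratios are not taken as those of unmethylated DNA. SLITRK1, a neuronal adhesion protein, had a ratio of 2.68 ± 0.12 (SD, n = 2) after SssI treatment, -0.79 ± 0.93 (n = 2) in brain and 0.05 on the GenomiPhi array. Its 5 probes lay on chromosome 13 from 83351617 to 83352010, inside the gene. GIN1 rose by 3.44 (SE 0.18) and the replication histone gene H3C3 by 3.43 (SE 0.25) over brain, and CFAP44, a protein of the ciliary axoneme, rose by 2.43 (SE 0.20) and the histone gene H2AC21 by 2.40 (SE 0.22) over the amplified control. Among 12829 genes tested with limma, 9318 were higher and 10 lower after SssI treatment than in brain, and 8830 were higher and 114 lower than on the GenomiPhi array. The genes that fell most were MRE11, which acts in repair of DNA breaks (-1.11, SE 0.30), ARRDC5 (-0.996, SE 0.21) and NEK1 (-0.97, SE 0.26) against GenomiPhi, and MGC12966 (-0.50, SE 0.11), MC3R (-0.35, SE 0.10) and CNGA4 (-0.27, SE 0.10) against brain. The median difference of all genes was 0.47 over brain and 0.43 over the GenomiPhi array. Within single scan days the medians were 0.49 and 0.42, and with scan day as a fixed term 7481 and 7042 genes passed. Centring on all probes in place of the brightest reference probes gave 5425 higher and 3285 lower against brain and 5021 and 1326 against GenomiPhi, and normexp background correction left 251 genes against GenomiPhi. Against GenomiPhi, centring on fragments without an HpaII site gave 12738 higher and 3 lower (median 1.12), and z-score means gave 12434 and 35. The HpaII channel alone kept the direction against brain (5023 higher and 2 lower, median 0.63) but not against GenomiPhi, where it gave 14 higher and 12 lower, a median of -0.32, and the same sign for 36.0% of the genes called; the deposited HpaII table gave 12 and 13 there.

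Genes measured only with all probes included CDKN2B, SFRP1 and GFAP. GFAP, the intermediate filament of astrocytes, read 0.72 ± 0.17 after SssI treatment, 0.01 ± 0.14 in brain, 0.66 ± 0.02 in U87MG and 0.56 ± 0.01 in glioblastoma (SD, n = 2 each). The tumour suppressor gene CDKN2B read 0.26 ± 0.08 after SssI treatment and -0.24 ± 0.09 in brain, and SFRP1, a WNT antagonist, read 0.17 ± 0.01 and -0.01 ± 0.14. Each had fewer than 3 responding probes, so these genes were outside the tests among brain, U87MG and glioblastoma that used the responding probes. H19 was not measured.

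**Figure D1:**
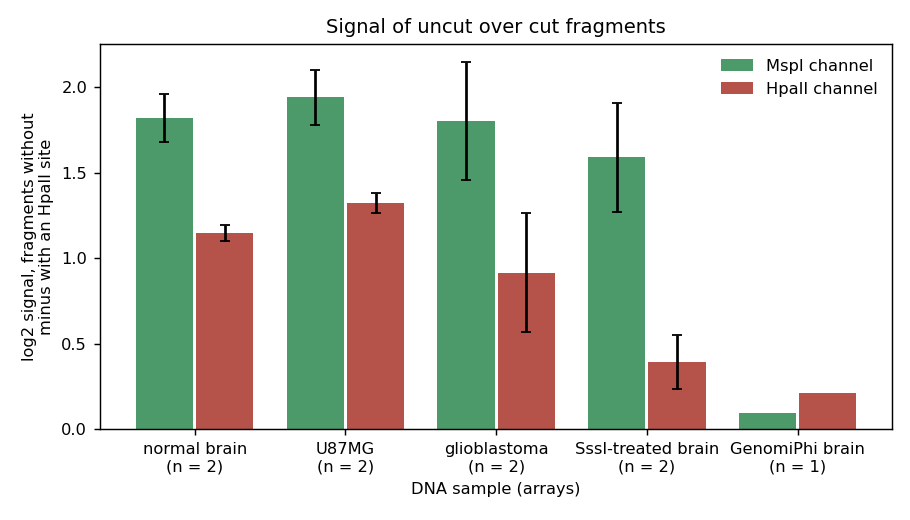
Median log2 signal of probes in BfaI fragments without an HpaII site minus that of probes in fragments with 1 or more, per DNA sample and channel (bars, mean over arrays; error bars, SD, n = 2; GenomiPhi, n = 1, no error bar). The MspI difference was 1.82 in normal brain and 0.095 on the GenomiPhi array.

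The amplified control, planned as the unmethylated reference, was compared with brain over 4630 genes with at least 3 probes that responded to SssI. Its contrast between fragments without and with an HpaII site was 0.095 in the MspI channel and 0.21 in the HpaII channel, so complete cutting of its DNA was not seen and its ratios are not taken as those of unmethylated DNA. The largest decreases after amplification included ZNF317, a zinc finger protein (chromosome 19, 9131888 to 9132569), which went from 2.27 ± 0.06 (SD, n = 2) to 0.23, SUN1, a nuclear envelope protein, from 1.90 ± 0.34 to -0.07, and NDUFS7, a subunit of respiratory complex I, from 1.98 ± 0.27 to 0.01. The largest increases were those of EPHA7, an ephrin receptor (1.95, SE 0.47), AHI1 (1.94, SE 0.41) and NCBP1, a cap binding protein (1.81, SE 0.39). By limma 727 genes were higher and 678 lower, 172 and 447 of them by at least 1. The direction depended on the scaling and on the channel, with 203 higher and 978 lower after centring on the responding probes, 6 and 1199 after centring on fragments without an HpaII site, and 408 and 752 after centring on all probes, while the HpaII channel alone gave 3064 higher and 55 lower and the deposited HpaII table gave 2901 and 49. With the compared groups alone 79 were higher and 656 lower. With scan day as a fixed term 1 gene passed, with normexp 0 passed (1530 at an unadjusted p under 0.05), and without normal brain replicate 2 the count was 874. The single GenomiPhi array has no spread of its own and was assumed to vary like the others.

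U87MG was compared with normal brain to find genes whose islands differ in a glioma cell line. FOXD1, a forkhead transcription factor of kidney and retina development, had the highest rise, from -0.53 ± 0.46 in brain to 3.53 ± 0.13 in U87MG (SD, n = 2 each), a 16.7-fold higher ratio at 5 probes downstream of the gene (chromosome 5, 72767867 to 72776581). AP3B2, a neuronal vesicle coat subunit, rose by 2.94 (SE 0.31), EID3, a subunit of the SMC5/6 complex, by 2.90 (SE 0.19), CLDN11, the claudin of myelin, by 2.74 (SE 0.23), POU4F1, a sensory neuron transcription factor, by 2.66 (SE 0.20), CMTM1 by 2.60 (SE 0.30), HOXD9 by 2.58 (SE 0.22) and FLJ26850 by 2.48 (SE 0.21). Lower in U87MG were DMRTB1, a transcription factor of the male germline, which fell by 2.13 (SE 0.21) from 2.10 ± 0.33 to -0.02 ± 0.15 at 6 probes inside the gene (chromosome 1, 53698274 to 53698918), and RBFOX3, the NeuN antigen of neurons, which fell by 2.12 (SE 0.20). GFRA2, a receptor for neurturin, fell by 2.06 (SE 0.22), SMPD3, a sphingomyelinase, by 2.05 (SE 0.18), TAFA5 by 2.02 (SE 0.17), APCDD1, a WNT inhibitor, by 1.97 (SE 0.24), GRM4, a metabotropic glutamate receptor, by 1.97 (SE 0.22) and NLRP4 by 1.90 (SE 0.24).

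Of 4630 genes tested in U87MG, 991 were higher and 203 lower than in brain by limma, 388 and 97 of them by at least 1. The median difference of all genes was 0.25. Every named gene called in a tumour comparison kept its sign relative to the all-gene median. That check could hardly fail, since the called differences exceeded these medians in size, and it says little about a shared offset. Scaling moved the split: centring on the responding probes gave 723 higher and 386 lower. With the HpaII channel alone it turned over, to 137 higher and 179 lower with an all-gene median of -0.16, and with the deposited HpaII table to 113 and 186 with -0.20. Over the responding probes the median log2 HpaII signal was 8.30 in brain and 8.20 in U87MG, and the MspI signal 8.21 and 7.83. In these medians the higher ratio in U87MG thus came with a lower MspI signal and not with a higher HpaII signal. The excess of higher genes is therefore not read as a gain of methylation. With scan day as a fixed term 554 genes passed, 450 higher and 104 lower. Within scan day A the all-gene median was 0.05 and within day B 0.47, and the genes called higher had medians of 0.67 and 1.14 there, the genes called lower -1.19 and -0.77. The all-gene median was 0.15 without U87MG replicate 2 and 0.14 without normal brain replicate 2. With normexp background correction 0 genes passed (54 at an unadjusted p under 0.05 by limma). The all-gene median was then -0.20, and 58.1% of the genes called above kept their sign (correlation of differences 0.728).

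Of 150 transcription factors of development outside the HOX clusters, 79 rose and 2 fell in U87MG (91 and 3 adjusted over the list alone) and 69 were not called, with a median difference of 0.59 against 0.25 for all genes and a camera adjusted p of 4.4e-08, a call lost with an estimated correlation (adjusted p = 0.981). FOXD1 and POU4F1 led the rises, while SOX8 fell by 1.09 (SE 0.19) and SALL3 by 1.00 (SE 0.19). Clustered protocadherins, cell surface proteins that give neurons their identity, had 13 of 25 members higher and none lower (15 adjusted over the list alone; median 0.68, camera adjusted p = 0.0139, and 0.981 with an estimated correlation). PCDHGA11 rose by 2.47 (SE 0.18) and PCDHGA12 by 2.35 (SE 0.19), the latter at 14 probes on chromosome 5 from 140787476 to 140792140. Without normal brain replicate 2 the members called higher numbered 53 and 6.

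Other fixed groups passed no camera test in U87MG with the ratios of the responding probes. Germline genes passed as lower with all probes (camera adjusted p = 0.043) and with the HpaII channel alone (camera adjusted p = 0.031). Over all genes tested 21.4% were called higher and 4.38% lower, beside which the counts below are to be read. HOX genes, which set position along the body axis, had 11 of 31 members higher (11 higher and 1 lower adjusted over the list alone), HOXD9 and HOXD4 (2.12, SE 0.21) among them. Neuron markers went both ways, 6 higher and 6 lower of 21 (the same counts adjusted over the list alone): SLC17A6, a vesicular glutamate transporter, rose by 1.96 (SE 0.22) and GAD1, which makes GABA, by 1.39 (SE 0.20), while RBFOX3 fell. Of 45 ion channels and receptors 13 were higher and 7 lower (13 and 7 adjusted over the list alone), with SSTR1 up by 1.65 (SE 0.17), KCNA4 up by 1.32 (SE 0.23) and CACNA1H down (-1.80, SE 0.20). Among 17 germline genes 4 were higher and 3 lower (4 and 3 adjusted over the list alone), BOLL (1.33, SE 0.17) and DDX4 (1.17, SE 0.18) against DMRTB1 and TEX101 (-1.78, SE 0.19). Promoters often discussed in glioma had 10 of 30 higher and 2 lower (11 and 2 adjusted over the list alone), with PCDHGA11 and TUSC3 (1.12, SE 0.17) up and DAPK1 (-1.54, SE 0.22) and NDRG2 (-0.58, SE 0.16) down. WNT antagonists had 6 of 13 higher (6 adjusted over the list alone), with SOX17 up by 1.74 (SE 0.18) and KREMEN2 by 1.52 (SE 0.19). Without normal brain replicate 2 the members called higher fell to 3 WNT antagonists, 8 ion channels and receptors and 6 promoters often discussed in glioma, and 1 such promoter was called lower (also 1 without U87MG replicate 1).

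Cell type markers, histone genes and imprinted genes also held called genes in U87MG, where 21.4% of all genes were called higher and 4.38% lower. The share called higher ran from 16.7% in the imprinted list to 55.6% in the endothelial and mesenchymal list. Of 9 endothelial and mesenchymal markers 5 rose and 1 fell (5 and 1 adjusted over the list alone), and TWIST1 rose by 2.17 (SE 0.24) while ETS1 fell by 0.72 (SE 0.17). CLDN11 and MBP (0.84, SE 0.19) were among 5 of 11 oligodendrocyte markers that rose (6 adjusted over the list alone), and PAX6 (1.00, SE 0.17), ID3 (0.73, SE 0.18) and NDRG2 were the 3 called of 6 astrocyte markers (2 higher and 1 lower adjusted over the list alone). In the immune list CD14 rose by 2.17 (SE 0.20), RUNX1 rose by 0.93 (SE 0.21) and ITGB2 fell by 1.49 (SE 0.21) among 8 genes (2 higher and 1 lower adjusted over the list alone). Among 12 histone genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), and H3C10 rose by 2.32 (SE 0.19), H2BC26 rose by 1.78 (SE 0.22) and H4C3 fell by 0.60 (SE 0.18). Of 18 imprinted genes 3 rose and 2 fell (3 and 2 adjusted over the list alone), and NNAT rose by 1.26 (SE 0.21), DLX5 rose by 0.85 (SE 0.24), KCNQ1 fell by 1.27 (SE 0.18) and SNRPN fell by 0.55 (SE 0.19). Without normal brain replicate 2 the members called higher were 2 oligodendrocyte markers, 2 histone genes, 1 imprinted gene, 1 astrocyte marker and 1 immune marker, and the lower calls of the histone and astrocyte lists were lost, while 1 imprinted gene was called lower. The same lower counts held without U87MG replicate 1. OLIG2, a factor of the oligodendrocyte lineage, rose by 0.73 (SE 0.18). The imprinted gene MEST differed by 0.14 (SE 0.18) and the cell cycle inhibitor gene CDKN2A by -0.19 (SE 0.20), neither of which passed. CDKN2A and CDKN2B are long reported missing from U87MG: the signal of both channels on the 4 probes there without an HpaII site fell by 3.88 (median, log2) against brain, while that of 11 reference probes there differed by 0.41 and that of all 78 probes by 0.071 (the 4 probes were singled out after this was seen), so the CDKN2A ratio in U87MG is not read as methylation.

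Glioblastoma was compared with normal brain to find genes that differ in tumour tissue. FOXD1 again led, with 2.25 ± 0.23 in glioblastoma against -0.53 ± 0.46 in brain (SD, n = 2 each; 6.89-fold), and BEND4 followed with a rise of 2.68 (SE 0.26; chromosome 4, 41847856 to 41849720, promoter and gene body). MCOLN2, an endosomal cation channel, rose by 2.53 (SE 0.34), DSC3, a desmosomal cadherin, by 2.48 (SE 0.18), CBLN2, a synapse organiser, by 2.44 (SE 0.35), GSC, the goosecoid homeobox gene, by 2.35 (SE 0.18), AP3B2 by 2.27 (SE 0.31) and PDGFD, a platelet-derived growth factor, by 2.27 (SE 0.27). The 24 lower genes included ADNP2, which fell by 1.67 (SE 0.29) from 1.74 ± 0.20 to 0.07 ± 0.11 at 3 probes downstream of the gene (chromosome 18, 76006215 to 76006656), and SYTL1, a Rab27 effector, which fell by 1.32 (SE 0.20). HSPB9 fell by 1.19 (SE 0.18), UVSSA, which acts in transcription-coupled repair, by 1.18 (SE 0.20), DAXX, a histone H3.3 chaperone, by 1.10 (SE 0.17), HOXA3 by 1.08 (SE 0.19), MOB3C by 1.00 (SE 0.21) and NR5A1, a steroidogenic factor, by 0.97 (SE 0.19).

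Glioblastoma had 830 genes higher and 24 lower than brain among 4630 tested by limma, 303 and 7 of them by at least 1, beside an all-gene median difference of 0.35. Centring on the responding probes, which sets that median to -0.01, gave 309 higher and 100 lower. Centring on fragments without an HpaII site gave 801 higher and 13 lower with a median of 0.43. The HpaII channel alone gave 147 higher and 4 lower with a median of 0.23. The count was 403 and 384 without glioblastoma replicates 1 and 2, 1329 without normal brain replicate 1, 341 without normal brain replicate 2, and 225 with normexp. The glioblastoma arrays shared no scan day with another group, so the day and the group cannot be told apart. With scan day as a random block 892 genes passed. That block cannot separate day from group either, and its estimated day correlation was negative (-0.20), so the count is no check on scan day.

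Of 150 developmental transcription factors, 100 rose and 1 fell in glioblastoma (125 and 1 adjusted over the list alone; median 0.77, camera adjusted p = 6.2e-18, and 0.981 with an estimated correlation), FOXD1 and GSC the most, with SOX8 the exception (-0.68, SE 0.19). Clustered protocadherins rose in 22 of 25 (23 adjusted over the list alone) by a median of 1.31 (camera adjusted p = 8.2e-16, and 0.981 with an estimated correlation), and their median level of 1.91 ± 0.02 lay near the 1.98 ± 0.01 of the SssI control (SD, n = 2 each). PCDHGA11 rose by 2.07 (SE 0.18) and PCDHGA12 by 2.04 (SE 0.19). HOX genes rose in 16 of 31 and fell in 1 (17 and 1 adjusted over the list alone; median 0.55, camera adjusted p = 0.0304, and 0.981 with an estimated correlation), HOXB2 by 2.14 (SE 0.24) and HOXD9 by 2.07 (SE 0.22) against HOXA3. The HOX call was also lost with promoter probes alone (adjusted p = 0.549). Without normal brain replicate 2 the members called higher numbered 62, 18 and 10, and SOX8 no longer passed.

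In glioblastoma the other 13 lists passed no camera test with the ratios of the responding probes. Neuron markers passed as higher with all probes (camera adjusted p = 0.043) and with z-score means (camera adjusted p = 0.0166). Promoters often discussed in glioma passed as higher with all probes (camera adjusted p = 0.043). Called members of these lists were nearly all higher, as were 97.2% of all called genes, and 17.9% of all genes tested were called higher. Ion channels and receptors rose in 12 of 45 (13 adjusted over the list alone), KCNA4 by 2.22 (SE 0.23) and GABRG3, a GABA receptor subunit, by 1.501 (SE 0.33). Neuron markers rose in 8 of 21 (10 adjusted over the list alone), SLC17A6 by 1.68 (SE 0.22) and GRIN2A, an NMDA receptor subunit, by 0.96 (SE 0.18). Imprinted genes rose in 8 of 18 and fell in 1 (9 and 1 adjusted over the list alone): PHLDA2 rose by 1.66 (SE 0.36), DIRAS3 by 1.22 (SE 0.32) and MEST by 0.54 (SE 0.18), KCNQ1 fell by 0.64 (SE 0.18), and SNRPN differed by 0.43 (SE 0.19) without passing. Among promoters often discussed in glioma 8 of 30 rose (10 adjusted over the list alone), among them PCDHGA11 and TUSC3 (1.37, SE 0.17). Germline genes rose in 6 of 17 (8 adjusted over the list alone), including TEX101 (0.86, SE 0.19) and BOLL (0.83, SE 0.17). Oligodendrocyte markers rose in 5 of 11 (6 adjusted over the list alone), CLDN11 by 1.83 (SE 0.23) and NKX2-2 by 1.11 (SE 0.20), and OLIG2 by 0.66 (SE 0.18). WNT antagonists rose in 4 of 13 (6 adjusted over the list alone), SOX17 by 1.71 (SE 0.18) and DKK2 by 0.67 (SE 0.18). Of 6 astrocyte markers 3 rose (4 adjusted over the list alone), SOX9 by 1.23 (SE 0.18) and PAX6 by 0.76 (SE 0.17). TWIST1 rose by 1.44 (SE 0.24) and ETS1 fell by 0.80 (SE 0.17) in the endothelial and mesenchymal list, where 3 of 9 rose and 1 fell (5 and 1 adjusted over the list alone). Housekeeping genes, taken as unmethylated in normal tissue, rose in 3 of 38 (0 adjusted over the list alone), SRSF1 by 0.75 (SE 0.22). Without normal brain replicate 2 the members called higher fell to 7 ion channels and receptors, 4 neuron markers, 3 imprinted genes, 2 germline genes, 2 oligodendrocyte markers, 1 WNT antagonist, 1 astrocyte marker and 0 housekeeping genes, and the lower call in the imprinted list was lost. CDKN2A differed by 0.02 (SE 0.20) and did not pass.

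**Figure D2:**
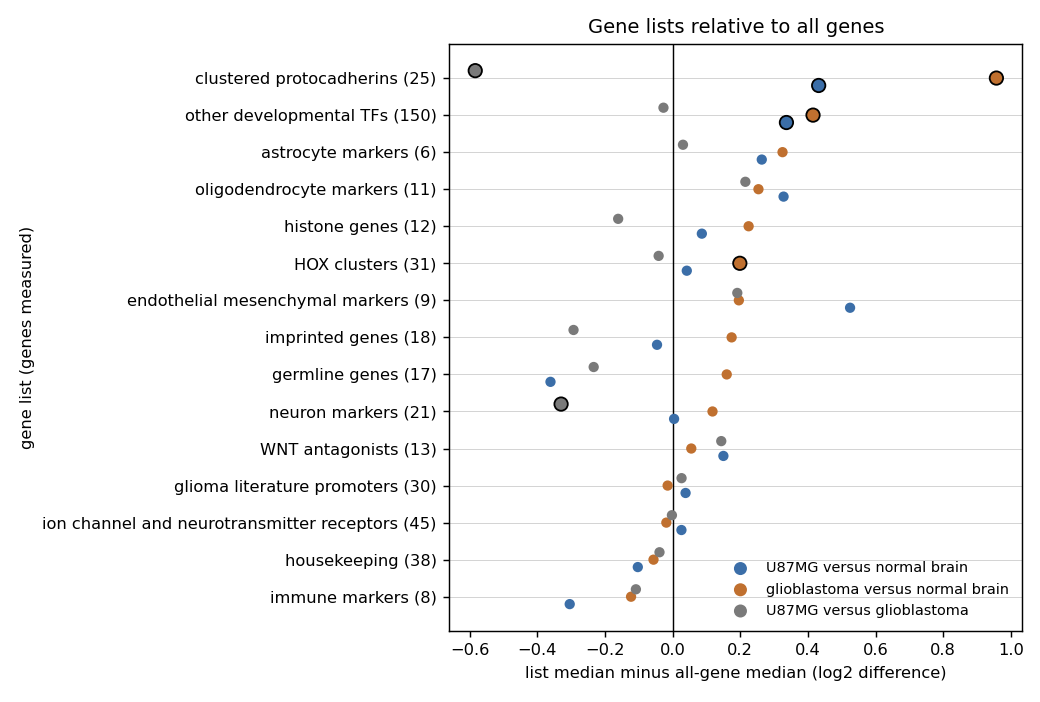
Median log2 difference of 15 fixed gene lists minus that of all genes tested, for 3 comparisons (points; number of genes measured in brackets; black outlines, camera adjusted p under 0.05 at the preset correlation). Protocadherins had the highest value against brain in glioblastoma, with a median difference of 1.31, and the lowest in U87MG against glioblastoma, with -0.69; no list passed with an estimated correlation.

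U87MG and glioblastoma were compared directly. ADNP2 was 2.90 ± 0.39 in U87MG and 0.07 ± 0.11 in glioblastoma (SD, n = 2 each), and EID3 was higher in U87MG by 2.68 (SE 0.19; 7 probes on chromosome 12, 103221376 to 103222222, promoter and gene body). FLJ26850 differed by 2.41 (SE 0.21), DCBLD1 by 2.25 (SE 0.22), PTGDR, a prostaglandin receptor, by 2.16 (SE 0.21), ZNF518A by 1.99 (SE 0.23), POU4F1 by 1.94 (SE 0.20) and C1orf141 by 1.91 (SE 0.18). Lower in U87MG were DMRTB1 (-2.67, SE 0.21), TEX101, a germ cell surface protein (-2.64, SE 0.19; chromosome 19, 48604021 to 48610946), RBFOX3 (-2.59, SE 0.20), APCDD1 (-2.57, SE 0.24), TGM6, a transglutaminase (-2.56, SE 0.21), TEKTL1 (-2.52, SE 0.25), MYT1, a zinc finger factor of neural differentiation (-2.51, SE 0.19), and TRIM71, a stem cell ubiquitin ligase (-2.44, SE 0.21). By limma 244 genes were higher and 401 lower in U87MG (91 and 200 by at least 1), with an all-gene median of -0.10. The split turned to 477 higher and 360 lower after centring on the responding probes and to 460 and 246 with z-score means. It kept its direction, with 110 and 501, after centring on fragments without an HpaII site, with 48 and 340 in the HpaII channel alone and with 1 and 444 after normexp. The all-gene median was 0.002 without U87MG replicate 1 and -0.20 without U87MG replicate 2. It was -0.08 and -0.12 without glioblastoma replicates 1 and 2. The lower all-gene median of U87MG was thus not seen without U87MG replicate 1, the array with the lowest MspI signal over background.

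Of 25 clustered protocadherins, 13 were lower in U87MG than in glioblastoma and none higher (16 lower and 1 higher adjusted over the list alone; median -0.69, camera adjusted p = 0.000175, and 0.981 with an estimated correlation), among them PCDHB15 (-1.44, SE 0.17) and PCDHGB3 (-1.40, SE 0.20). Neuron markers were lower in 7 of 21 (7 lower and 1 higher adjusted over the list alone; median -0.43, camera adjusted p = 0.0304, and 0.981 with an estimated correlation), among them RBFOX3 and KCNC1, a potassium channel (-2.17, SE 0.20). The neuron call was also lost with all probes (adjusted p = 0.0537) and with z-score means (adjusted p = 0.736). Without U87MG replicate 1 the members called lower fell to 6 protocadherins, 10 developmental transcription factors, 7 ion channels and receptors and 0 histone genes. Developmental transcription factors had 9 members higher and 22 lower (10 and 26 adjusted over the list alone), FOXD1 up by 1.28 (SE 0.23) and POU4F1 up, GSC (-2.07, SE 0.18) and SALL3 (-1.52, SE 0.19) down. HOX genes had 3 higher and 3 lower (4 and 7 adjusted over the list alone; 6 lower without normal brain replicate 2, which enters only through the shared spread), HOXC6 (0.92, SE 0.18) and HOXB5 (0.87, SE 0.18) up, HOXB2 (-1.90, SE 0.24) and HOXA13 (-1.22, SE 0.17) down. Ion channels and receptors had 2 higher and 13 lower (3 and 14 adjusted over the list alone), with SSTR1 (0.95, SE 0.17) and GALR3 (0.69, SE 0.18) against GRM4 (-2.08, SE 0.22) and KCNK9 (-1.98, SE 0.21). Germline genes had 6 lower (6 lower and 1 higher adjusted over the list alone), and of 18 imprinted genes 3 were lower (4 adjusted over the list alone), among them DIRAS3 (-1.62, SE 0.32) and SNRPN (-0.99, SE 0.19). Over all genes tested 5.27% were called higher and 8.66% lower, beside 9.68% and 9.68% of HOX genes. Germline genes passed as lower with all probes (camera adjusted p = 0.043) and with the HpaII channel alone (camera adjusted p = 0.024). Ion channels and receptors passed as lower with the HpaII channel alone (camera adjusted p = 0.017). WNT antagonists had KREMEN2 (0.88, SE 0.19) and SFRP4 (0.67, SE 0.17) higher and DACT2 (-0.99, SE 0.19) lower (3 higher and 1 lower adjusted over the list alone). Histone genes had H3C10 (1.80, SE 0.19) and H2BC26 (1.19, SE 0.22) higher and H3C12 (-0.94, SE 0.27) and H4C3 (-0.72, SE 0.18) lower (2 and 2 adjusted over the list alone). Of 30 promoters often discussed in glioma, 1 was higher and DAPK1 (-1.80, SE 0.22) and DIRAS3 were lower (1 and 2 adjusted over the list alone). MEST (-0.40, SE 0.18), OLIG2 (0.07, SE 0.18) and CDKN2A (-0.21, SE 0.20) did not pass.

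**Figure D3:**
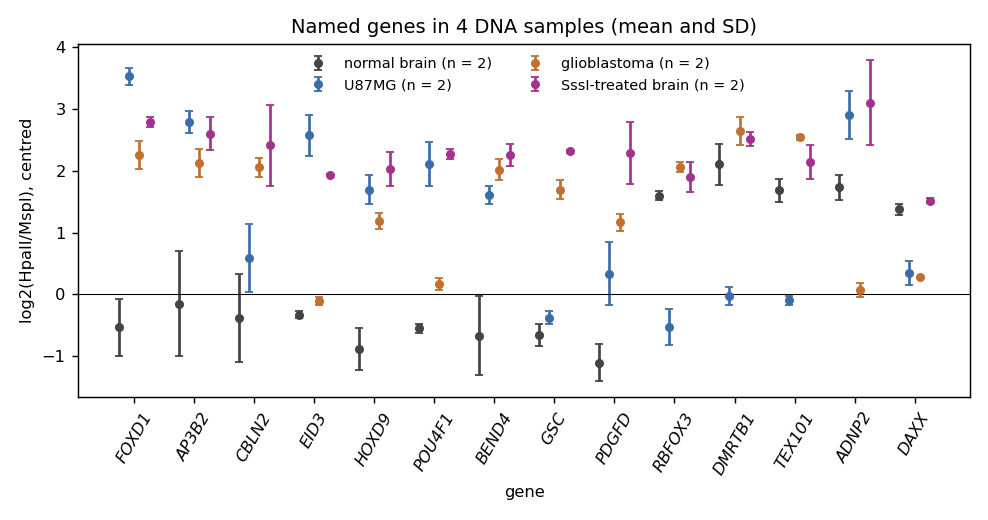
Centred log2 ratio of HpaII over MspI signal for 14 named genes in 4 DNA samples (points, mean; error bars, SD, n = 2 arrays). FOXD1 read -0.53 in normal brain, 3.53 in U87MG and 2.25 in glioblastoma, and DMRTB1 read 2.10 in normal brain and -0.02 in U87MG.

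U87MG and glioblastoma calls against brain were set side by side. FOXD1, AP3B2, HOXD9, SOX17, TWIST1 and PCDHGA11 were among 460 genes called higher in both, and ETS1, KCNQ1 and SOX8 among 11 called lower in both. In opposite directions went 28 genes, 4 of them higher in U87MG, such as ADNP2, and 24 lower in U87MG, such as TEX101. From the sizes of the lists alone 178 and 1.05 shared genes would arise, a figure that does not allow for the brain arrays that both comparisons used. In 20 simulations of unchanged groups with the same brain arrays at most 0 genes were called in both, a value that leaves out the real differences. Across genes the covariance of the differences was 0.103, against 0.0218 in the simulations (correlation 0.490, against 0.503). With 1 brain array given to each comparison, so that none was shared, it was 0.0849 and 0.0772 in the 2 ways of dividing them (values without a test, computed after the other results were seen). Noise of the shared arrays thus brought only part of the covariance. Both brain arrays held the same DNA, so features of that DNA remain shared, and part of the overlap may come from the shared controls. Of the 460 genes higher in both, 404 were not called different between U87MG and glioblastoma.

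**Figure D4:**
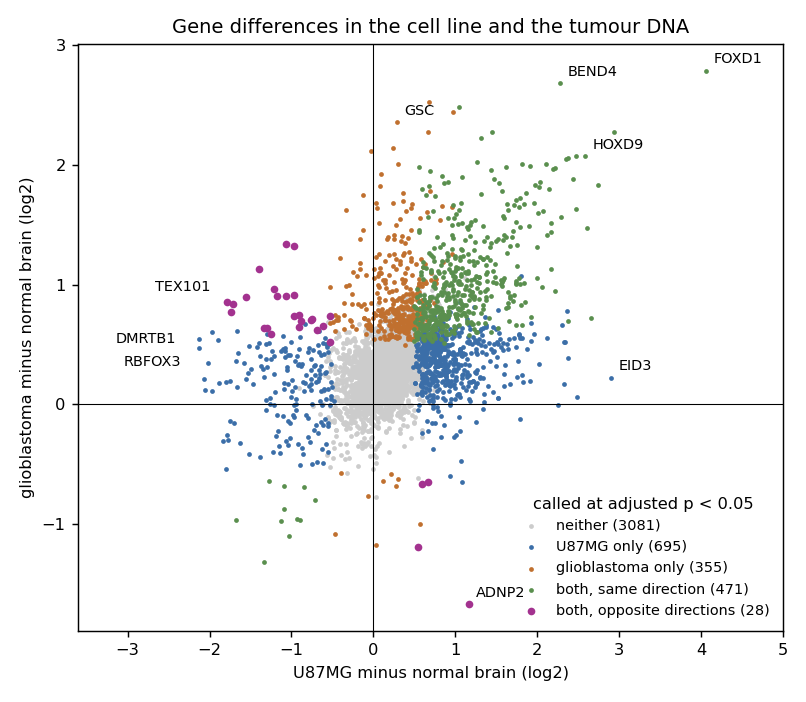
Difference from normal brain in glioblastoma against that in U87MG (log2, 1 point per gene, 4630 genes; colours, genes called at adjusted p under 0.05 in neither, 1 or both comparisons). The 28 genes called in opposite directions include TEX101 and ADNP2; both axes share the normal brain arrays.

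Levels were also placed between the controls, with the GenomiPhi value as 0 and the SssI value as 1 on the log2 scale; this is a position and not a percentage of methylation, and with the small site contrast of the GenomiPhi array (0.095 in the MspI channel) 0 does not stand for unmethylated DNA. Of 4626 genes, 80.0% ± 3.1 lay under 0.25 in brain, 71.4% ± 4.7 in U87MG and 68.3% ± 0.41 in glioblastoma, and 6.89% ± 2.1, 11.7% ± 2.3 and 13.7% ± 0.76 lay over 0.75 (SD, n = 2 arrays each). Many genes lay below the GenomiPhi value, 67.6% in brain, 52.2% in U87MG and 44.4% in glioblastoma. Imprinted genes, methylated on 1 parental copy in normal tissue, had a median ratio of 0.95 ± 0.08 in brain, 0.43 ± 0.15 in U87MG and 0.94 ± 0.14 in glioblastoma, against 0.16 on the GenomiPhi array and 1.83 ± 0.09 after SssI treatment. The median of the differences from brain of the 18 imprinted genes, taken gene by gene, was 0.20 in U87MG and 0.53 in glioblastoma. Germline genes, methylated in most normal tissues, had 0.97 ± 0.00 in brain, 0.94 ± 0.13 in U87MG and 1.33 ± 0.13 in glioblastoma, and housekeeping genes -0.18 ± 0.16, -0.10 ± 0.23 and 0.08 ± 0.02. No test was run on these levels.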

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

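The tests on the noise of a single array and the selection of these differences were made after the results were seen; the test on copy number was set down before its result was known. The differences between U87MG and glioblastoma below were tested with limma, or with camera for the lists.

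Against brain, 28 genes went in opposite directions in the 2 tumour samples. ADNP2 was higher in U87MG than in glioblastoma by 2.83, having risen in U87MG and fallen in glioblastoma against brain, and EID3 was higher in U87MG by 2.68. TEX101 differed by -2.64, with a fall in U87MG and a rise in glioblastoma, and the homeobox gene GSC differed by -2.07. The protocadherin list differed by a median of -0.69 and the neuron marker list by -0.43, both calls being lost with an estimated correlation and the neuron call also with z-score means. The comparisons with brain share the brain arrays with each other and the U87MG and glioblastoma arrays with the direct comparison, so the direct differences of genes chosen on those arrays are no independent support.

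BfaI fragments whose probes name no gene were outside the gene tests. Their median ratio was 0.44 ± 0.02 in glioblastoma (SD, n = 2), against 0.01 ± 0.12 in brain, 0.14 ± 0.11 in U87MG and 0.15 on the GenomiPhi array. Their median difference from brain in glioblastoma, 0.37, was near the 0.36 of promoter fragments and the 0.34 of fragments inside genes, so their median did not stand out. Their shares of rises (19.1%) and falls (2.32%) there were above those of promoter fragments (12.7% and 0.276%) and of fragments inside genes (13.4% and 1.17%). Of 1421 such fragments 272 were higher and 33 lower in glioblastoma than in brain, and 341 were lower and 92 higher in U87MG than in glioblastoma. The highest in glioblastoma over brain lay on chromosome 15 from 87750803 to 87751326 (3.80, SE 0.46), and it was also higher in U87MG (3.67, SE 0.46).

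The genes lower in U87MG than in brain, such as DMRTB1, RBFOX3 and TEX101, were weighed as a pattern. Loss of DNA copies over the 1 Mb around these genes was argued against. On fragments without an HpaII site in that range the signal of both channels differed from brain by a median of 0.11 (bootstrap interval 0.08 to 0.16). This was close to the 0.11 of all genes, and 164 of 203 genes had 3 or more such probes. At CDKN2A and CDKN2B, long reported missing from this line, the signal fell by 3.88 on 4 probes of such fragments. That value was taken at the genes themselves and not over 1 Mb. It therefore does not show that the 1 Mb median would reveal a loss of a single gene. The check at CDKN2A and CDKN2B was first made over all 78 probes there, where the median was 0.071 and no loss showed. It was narrowed to the 4 probes after this was seen. Noise of the weakest array was argued against as well: the 203 genes lowest on scan day A lay at -1.23 relative to all genes on day B, and those lowest on day B at -1.22 on day A. Loss of methylation in U87MG may be the source of these differences, as a hypothesis found and tested on the same data. What stays open is the background correction, since normexp left 0 genes in this comparison, and a loss of copies confined to single genes. Also open is whether the change is of tumour or of culture, which the design does not separate.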

How the results depend on the processing

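Alternatives added after seeing the data were the centring on responding probes and on fragments without an HpaII site, the z-score means, scan day as a block, the GenomiPhi array left out and promoter probes only. Of 157 named gene values, 156 kept direction and side of the threshold with scan day as a random block, 153 with centring on all probes, 131 of 145 with centring on responding probes and 44 with normexp, where 85 no longer passed and 25 reversed; the cause of the changes below was not tested unless stated. The random block is no check on scan day for glioblastoma, whose arrays shared no day with another group. Its estimated day correlations were negative, -0.20 with the responding probes and -0.10 with all probes. Low MspI signal over background, 2.60 over all probes in U87MG replicate 1, limits all ratios. The responding probes were dimmer still in that channel.

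With the HpaII channel alone the counts were 26 for SssI against GenomiPhi, 5025 for SssI against brain, 3119 for GenomiPhi against brain, 316 for U87MG against brain, 151 for glioblastoma against brain and 388 for U87MG against glioblastoma. The deposited HpaII table gave 25, 4513, 2950, 299, 128 and 425 in that order. Single probes, of which more were tested, gave 78313, 57186, 3277, 4832, 2214 and 3154. Normexp gave 251 for SssI against GenomiPhi, 0 for GenomiPhi against brain (1530 at an unadjusted p under 0.05), 0 for U87MG against brain (54) and 225 for glioblastoma against brain. A threshold of 2 for responding probes, which tests fewer genes, gave 333, 214, 241 and 97 in the last 4 comparisons. Glioblastoma against brain gave 525 with all probes, 409 with centring on the responding probes and 243 with z-score means, U87MG against brain 715 with centring on fragments without an HpaII site and 554 with scan day as a fixed block, and U87MG against glioblastoma 1009 with a minimum of 1 probe. GenomiPhi against brain gave 735 with the compared groups alone, 4918 with z-score means and 1 with scan day as a fixed block. Leave-one-out counts ranged from 8028 to 8077, 8345 to 8515, 874 to 1611, 707 to 1397, 341 to 1329 and 353 to 600 in the order above; the lone array of a group was then assumed to vary like the others.

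Of 7 list calls, 0 held with an estimated correlation (adjusted p = 0.981 each; 0 also after centring on the responding probes, adjusted p from 0.229 to 0.71) and 2 with promoter probes only, where 3 of the calls could be tested. The share of genes under a position of 0.25 was 89.6% in brain, 88.7% in U87MG and 85.0% in glioblastoma with the HpaII channel alone (1391 genes, against 4626), and 85.8% in brain and 70.8% in glioblastoma with a threshold of 2 (662 genes). Over 0.75 lay 4.67%, 5.39% and 7.66% with the HpaII channel alone, and 12.0% in glioblastoma with a threshold of 2. Leave-one-out shares ranged from 77.8% to 82.2% and 5.43% to 8.34% in brain, 68.1% to 74.8% and 10.1% to 13.3% in U87MG, and 68.0% to 68.5% and 13.2% to 14.3% in glioblastoma. Genes called in the same direction in both tumour comparisons numbered 471, and 144 at differences of at least 1.

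Reversed in sign with the HpaII channel alone were MRE11 (0.33) and NEK1 (0.43) in SssI against GenomiPhi and CNGA4 (0.025) and MGC12966 (0.43) in SssI against brain; the deposited table gave 0.44, 0.44, 0.023 and 0.45. With z-score means AHI1 (-2.67), EPHA7 (-0.78) and NCBP1 (-1.30) reversed in GenomiPhi against brain, MEST (-0.10) in glioblastoma against brain and H3C12 (0.011) in U87MG against glioblastoma. With normexp CNGA4 (0.27) and MC3R (0.31) reversed in SssI against brain, and NDUFS7 (0.011) and ZNF317 (0.52) in GenomiPhi against brain. In U87MG against brain, where normexp put the all-gene median at -0.20, it gave DLX5 (-0.032), FLJ26850 (-0.055), ID3 (-0.12), OLIG2 (-0.054), RUNX1 (-0.039), SOX17 (-0.00659) and TUSC3 (-0.087). In glioblastoma against brain it gave ETS1 (0.081), HSPB9 (0.067), KCNQ1 (0.080), MOB3C (0.038) and PHLDA2 (-0.050). In U87MG against glioblastoma, with an all-gene median of -0.36, it gave FLJ26850 (-0.023), FOXD1 (-0.50), GALR3 (-0.25), H3C10 (-0.11), HOXB5 (-0.049), HOXC6 (-0.15), KREMEN2 (-0.16), SFRP4 (-0.13) and SSTR1 (-0.29).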

Other observations

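Fragments were tested by their place relative to genes. Fragments downstream of genes had the highest share of rises in both tumour samples, 27.8% of 396 in glioblastoma and 30.3% in U87MG, against 12.7% and 16.9% of 2174 promoter fragments. Falls in U87MG made up 16.7% of 1421 fragments that name no gene and 1.52% of promoter fragments. In the lists not described above, housekeeping genes rose in 2 of 38 in U87MG (1 adjusted over the list alone; 5 without U87MG replicate 1 and 1 without normal brain replicate 2), immune markers in 2 of 8 in glioblastoma (3 adjusted over the list alone) and histone genes in 2 of 12 in glioblastoma (7 adjusted over the list alone; 0 without normal brain replicate 2). Between U87MG and glioblastoma, 0 of 38 housekeeping genes and 0 of 9 endothelial and mesenchymal markers passed in limma, and 1 of 6 astrocyte, 2 of 11 oligodendrocyte and 2 of 8 immune markers did.

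At CDKN2A and CDKN2B, 3 of the 4 probes in fragments without an HpaII site were lower in U87MG than in brain by more than 1 on the log2 scale, and 0 of 11 reference probes there were. The reference probes were chosen for the highest MspI signal on all arrays. At these genes, long reported missing from U87MG, their signal differed from brain by a median of 0.41, so there it did not follow a loss of copies. Of all 78 probes there, 11 were lower by more than 1. Whether reference probes elsewhere follow the local DNA was not tested. As they centre every main value, this limits the measure.

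All tests in the next 2 paragraphs were chosen after the results were seen.

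The GenomiPhi array showed little contrast between fragments with and without HpaII sites. Its MspI signal on fragments without a site was 0.095 above that on fragments with sites, against 1.36 or more on every other array, so undigested or carried-over amplified DNA in both portions could be the source. Complete cutting of unmethylated DNA was argued against by the HpaII difference of 0.21, lower than the 1.15 ± 0.05 (SD, n = 2) of brain. Weak hybridisation was argued against by an MspI signal 27.8 times above background, the highest of the 9 arrays. What this means for the place of 0 on the scale between the controls stays open, and no biological explanation was tested.

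Most genes that differed between glioblastoma and brain were higher. An offset shared by all responding probes may account for part of it: housekeeping genes had a median difference of 0.30, close to the 0.35 of all genes. The developmental transcription factors exceeded the housekeeping genes by at least 0.42 in each of the 4 pairs of arrays and the protocadherins by at least 0.88. An offset of equal size at all responding probes would not give such an excess. These lists were chosen for their medians on the same arrays, and the pairs reuse the same technical replicates, so the comparison is no independent test. An offset that differs between probes was not tested. Normal brain replicate 2 alone was argued against, since without it the all-gene median was 0.25. A gain of methylation in these lists in glioblastoma stays a hypothesis, with scan day confounded with the group.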
